A study of Mus musculus with 6 samples.

How the data were processed

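Small RNA from the uterus of ovariectomized C57BL/6 mice was profiled on 6 single-colour spotted microRNA (miRNA) arrays, 3 from the vehicle control group and 3 from the estradiol (E2) group. Per the labels' protocols, 100 µg of total RNA was size-fractionated to isolate the miRNA fraction, which was labelled with Cy5 through an amine-reactive dye kit. The arrays belong to 2 platforms. Replicates 1 and 2 of each group were hybridised to the 4-array platform, and replicate 3 of each group to the 2-array platform.

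Per the file headers, each array's own file holds raw spot intensity, with no background column. The scanner, the spot-finding software and the hybridisation are not given in the sources used here. On the 4-array platform each of 661 features was printed as 4 spots, beside 194 empty spots and a bright feature printed 18 times among them. On the 2-array platform each of 380 features was printed as 3 spots, beside a bright feature printed 12 times. The files do not say what the repeated bright features are. They were treated as controls and left out of normalization and tests, as were 3 features of the 2-array platform that the authors' table omits. The deposited value tables hold intensity that the authors had normalized. Comparison of these tables with the raw spots showed that 95.5% to 97.6% of the values of an array equalled the mean of the feature's spots times a single factor, within 0.1%. The factor set the median of all spots to 154 on the 4-array platform and to about 168 on the 2-array platform. Nearly all remaining values equalled the same product after some spots had been left out. No background had been subtracted and no log taken. Because most spots lie at background, this scaling equalises the background of the arrays and leaves differences in overall signal in place.

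The feature IDs carry no miRNA names. None of the IDs occurs in the reference gene table (GRCm38.p6), and the 2 platforms share 0 IDs, so features are reported by ID and replicate 3 could not be joined to replicates 1 and 2. The planned fit over all 6 arrays, which required 50 shared miRNAs, and the planned tests of 21 fixed miRNA lists (families, clusters and cell type markers) were therefore not run. The plan then made the 4-array platform the main comparison. The species each feature was designed for is likewise not given in the sources used here, and all features were kept.

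For the main comparison the raw spot intensities were averaged per feature, transformed to log2 and quantile-normalized across the 4 arrays. A feature counted as above background on an array when its mean exceeded the 95th percentile of that array's empty spots. Features above background on both arrays of at least 1 group were tested with limma (lmFit and eBayes, two-sided, 2 residual degrees of freedom before moderation), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2-array platform has no empty spots, and there the threshold was the median of all features plus 3 median absolute deviations. With 1 array per group on that platform, only values are given. Net signal is the mean intensity minus the array's background, which was the median of the empty spots or, on the 2-array platform, of all features. Where a feature was not above background in a whole group, the fold is a lower bound, computed against the higher of its own signal and the lowest signal above background on that array and scale. A difference of the array medians of log2 net signal was tested by exact permutation of the arrays within platform.

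The comparisons, the quantile normalization, the test and most alternatives were fixed before the data were examined. The rule for naming features, also fixed then, allowed several per direction by size or by p. Since no names were at hand, it was shortened to the 2 of smallest unadjusted p in each direction on the 4-array platform. On the 2-array platform the features named are the largest decrease and the 2 largest increases after quantile normalization, plus the brightest feature, which was chosen after its values were seen. Alternatives tried were cyclic loess, median centring, no normalization between arrays, the authors' processed values, other filters on dim features, the replicate number as a block, another variance model, a threshold of 0.10, and leaving out each array. The number of arrays limits the precision. The labels do not say whether an array holds RNA of a single animal, so p-values measure only the spread between these samples. The fitting code was tested on simulated data drawn from the real feature means and spreads. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 were used.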

Results

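The series asked how estradiol (E2), the main ovarian estrogen, alters the miRNA content of the mouse uterus. Wild-type females (WT in the sample titles) were ovariectomized at 15 weeks of age, which removes the source of ovarian hormones. The labels give an age of 16 weeks for replicates 1 and 2 of each group and none for replicate 3. Uteri of the E2 group were collected 24 hours after E2 at 0.050 mg per kg body weight per day, and those of the other group served as vehicle controls. Each group comprised 3 arrays, of which replicates 1 and 2 were on the 4-array platform and replicate 3 was on the 2-array platform. Most features of each array lay at background. On the 4-array platform, 213 of 661 features were above background on vehicle 1, 112 on vehicle 2, 88 on E2 replicate 1 and 106 on E2 replicate 2. With the rule of the 2-array platform (median plus 3 median absolute deviations) the shares above background were 19.4%, 17.1%, 14.4% and 16.9%, against 32.2%, 16.9%, 13.3% and 16.0% with the empty spots, so that most of the excess on vehicle 1 rested on the empty-spot threshold. Vehicle 1 also had the lowest empty spots, with a median of 143.7 against 212.6, 181.4 and 185.4 on the other arrays. On the 2-array platform, 49 of 377 features were above background on vehicle 3 and 18 on E2 replicate 3. Spots of a feature differed by a median coefficient of variation between 5.27% and 11.1% within an array.

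At the authors' scale, the detected features of the 4-array platform were lower on the E2 arrays nearly throughout. Of the 80 features above background on all 4 arrays, 79 had a lower mean log2 net signal with E2, and the median difference was -1.43 on the log2 scale (SD across features 0.44), or 2.69-fold lower. This held over the whole range of brightness. The median was 2.41-fold lower for the 20 dimmest features (19 lower) and 2.70-fold lower for the 20 brightest (20 lower). The E2 arrays also differed from each other by almost as much. All 80 features were lower on E2 replicate 1 than on E2 replicate 2, by a median of 1.29 on the log2 scale, whereas the vehicle arrays differed by a median of 0.42. Against vehicle 1, the median feature was 4.33-fold lower on E2 replicate 1 and 1.90-fold lower on E2 replicate 2. Against vehicle 2, it was 3.34-fold and 1.5-fold lower. The bright feature printed 18 times, in contrast, read 33911 ± 3427 and 38536 ± 3772 on the vehicle arrays and 34201 ± 2142 and 38525 ± 2696 on the E2 arrays (raw intensity, SD over spots).

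**Figure D1:**
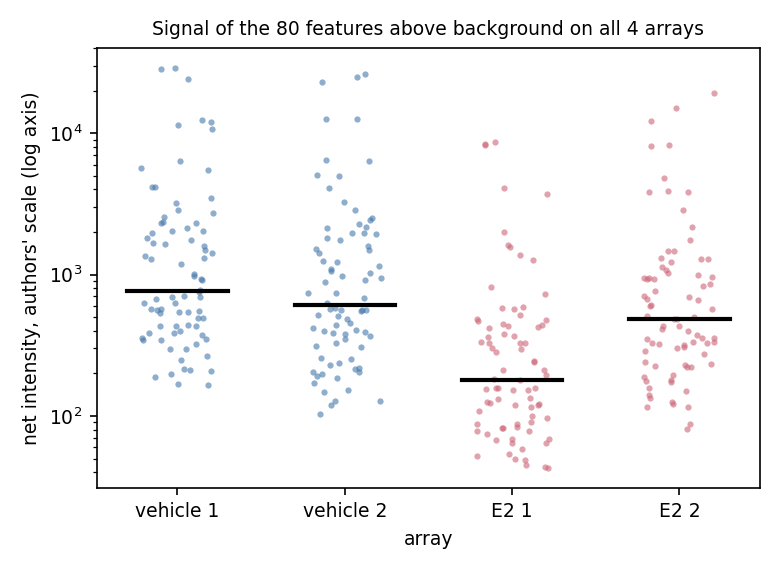
Net intensity at the authors' scale (log axis) of the 80 features above background on all 4 arrays of the 4-array platform. Each point is a feature, black bars are array medians (761, 607, 180 and 485.9 from left to right), and the lowest array is E2 replicate 1.

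When the array medians were compared within platforms over all 6 arrays, net signal was 0.86 lower with E2 on the log2 scale, or 1.81-fold. This is a mean of the 2 platforms' differences weighted by arrays per group. The platforms were unlike, at 2.30-fold lower over 80 features on the 4-array platform and 1.13-fold lower over 9 on the other. The difference was -1.20 on the 4-array platform, where the SD (n = 2) was 0.23 for vehicle and 1.01 for E2. On the 2-array platform it was -0.18, from median net signals of 157.2 on vehicle 3 and 138.9 on E2 replicate 3. The vehicle 3 median was the value of PS20139, whose spots there disagreed (raw 326.2, SD 240.5 over 3 spots). The authors' values for PS20139, with spots left out, were 186.3 on vehicle 3 and 269.8 on E2 replicate 3. The next lower feature of the 9 on vehicle 3, PS20264, was at 127.7, so the sign of the -0.18 rests on PS20139. The pooled value and the p-value below were not recomputed without PS20139. The exact permutation test within platforms gave p = 0.167 (two-sided), which is the smallest value that its 12 arrangements allow, so this test could not pass a 0.05 threshold here.

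The same dependence on the arrays appeared when the authors' processed values were tested feature by feature. Of 112 features tested, 98.2% were lower with E2, and 29 fell while 0 rose at an adjusted p under 0.05 (limma, Benjamini-Hochberg). In 91 of the 112 features both E2 arrays lay below both vehicle arrays, and in 0 both lay above, where chance gives 16.7% in each direction for independent features. That share does not allow for the filter. Only 80 of the 112 were above background on all 4 arrays, and most others entered through the vehicle arrays, which favours lower values. The number called was 3 without E2 replicate 1, 81 without E2 replicate 2, and 0 without either vehicle array. These fits leave 1 array in a group, whose spread is assumed to be that of the other group. With the replicate number as a block, 0 features were called. The fit gave all features a common spread, so a difference shared by all features of an array entered every one of these tests.

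After quantile normalization, which sets the overall signal of the arrays equal and was the main setting, no individual feature passed the test. Among the 112 features, 40 were higher, 70 lower and 2 equal between the groups, and 0 passed an adjusted p of 0.05 with limma, while 12 had an unadjusted p under 0.05. The smallest adjusted p was 0.175. Differences ran from -0.57 to 0.77 on the log2 scale, and the median 95% confidence interval reached 0.41 to either side. No feature differed by more than 1 on the log2 scale in either direction, and 108 differed by less than 1.5-fold. Both E2 arrays lay below both vehicle arrays in 30 features and above in 14, but among the 80 features above background on all 4 arrays the counts were 14 and 12, so most of that tilt came from features at background on an E2 array. The profiles were close to each other whatever the group. Across the 80 features, which are not independent replicates, Pearson's r of log2 net signal was 0.966 between the vehicle arrays, 0.974 between the E2 arrays and 0.947 to 0.973 between arrays of different groups.

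**Figure D2:**
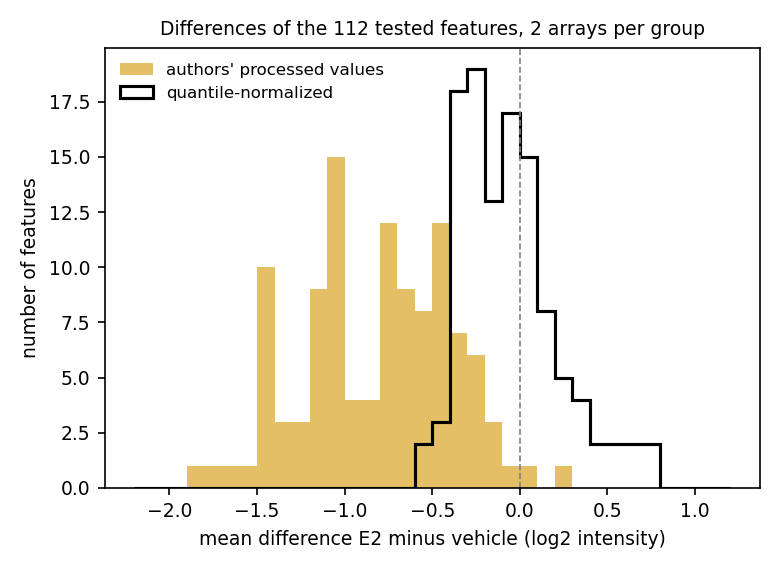
Histogram of the mean log2 difference, E2 minus vehicle, of the 112 tested features of the 4-array platform (2 arrays per group; vertical axis, number of features). With the authors' processed values (filled) 98.2% lie below 0, and after quantile normalization (line) the median is -0.09.

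The features of smallest p were examined on both scales. BM10206 had a quantile-normalized log2 intensity of 10.29 ± 0.00 with vehicle and 11.06 ± 0.03 with E2 (SD, n = 2), a difference of 0.77 (SE 0.14, limma adjusted p = 0.175), or 1.71-fold. The sign turned with the authors' processed values, where its difference was -0.52 (SE 0.44). Those values were 1788 and 1380 on the vehicle arrays and 744 and 1617 on the E2 arrays. The SD of 0.00 thus reflects an equal rank on both vehicle arrays, which quantile normalization turns into equal values, and not equal measurements. With the median of the spots in place of their mean, an alternative chosen after seeing the data, BM10206 passed after quantile normalization (difference 0.70, limma adjusted p = 0.0298). BM10653 was 1.49-fold higher after quantile normalization (difference 0.57, SE 0.16, limma adjusted p = 0.337) and likewise lower, by -0.43, at the authors' scale. BM10188 was lower on both scales. Its difference was -0.57 (SE 0.17, limma adjusted p = 0.337) after quantile normalization and -1.52 with the authors' values, where it passed (limma adjusted p = 0.0116), though not with the replicate number as a block (limma adjusted p = 0.0813). BM10070 was above background on both vehicle arrays and on neither E2 array, so that only a bound could be given, at least 1.23-fold lower after quantile normalization and at least 1.71-fold lower at the authors' scale.

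On the 2-array platform, fewer features were above background with E2. Of the 58 features above background on at least 1 array, 40 were above it on vehicle 3 only, 9 on E2 replicate 3 only and 9 on both. At the authors' scale 45 of the 58 were lower on the E2 array (77.6%), and after quantile normalization 63.8% were. The exact binomial 95% interval was 50.1% to 76.0%. It covers counting error only and treats the features as independent, which features of the same arrays are not. Most of the 58 entered through vehicle 3 alone, which favours lower values with E2. After quantile normalization the share was 43.0% with no filter and 0% for the 9 features above background on both arrays, so the direction turned with the filter. Of the 9 features above background on both arrays, 6 had lower net signal with E2. The median difference over the 9 was -0.77 on the log2 scale (interquartile range -1.91 to 0.38). Among the 6 was PS20139, whose vehicle 3 spots disagreed (raw 326.2, SD 240.5). In the authors' values, with spots left out, PS20139 was higher with E2 (186.3 on vehicle 3 and 269.8 on E2 replicate 3). The bright feature printed 12 times was itself 1.82-fold lower on the E2 array, at 25785 ± 1956 against 46907 ± 3644 (raw intensity, SD over spots). When both arrays were set equal on it, 53.4% of the 58 features were lower. There was no replicate on this platform, and no test was made.

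The brightest feature of vehicle 3 apart from that control, PS20145, read 29488 at the authors' scale on vehicle 3 and 1147 on E2 replicate 3, which is 25.7-fold lower, and 14.6-fold lower when scaled by the control. It was the brightest feature on both arrays, so quantile normalization set its difference to 0. PS20122 was above background on vehicle 3 (1108 at the authors' scale) and not on E2 replicate 3, at least 4.67-fold lower at that scale and at least 1.74-fold lower after quantile normalization. In the other direction, PS20371 read 286.5 on vehicle 3 and 409.0 on E2 replicate 3 at the authors' scale, 1.43-fold higher, or 3.11-fold after quantile normalization. PS20466 was above background only on E2 replicate 3, at least 1.19-fold higher at the authors' scale and at least 2.55-fold after quantile normalization.

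**Figure D3:**
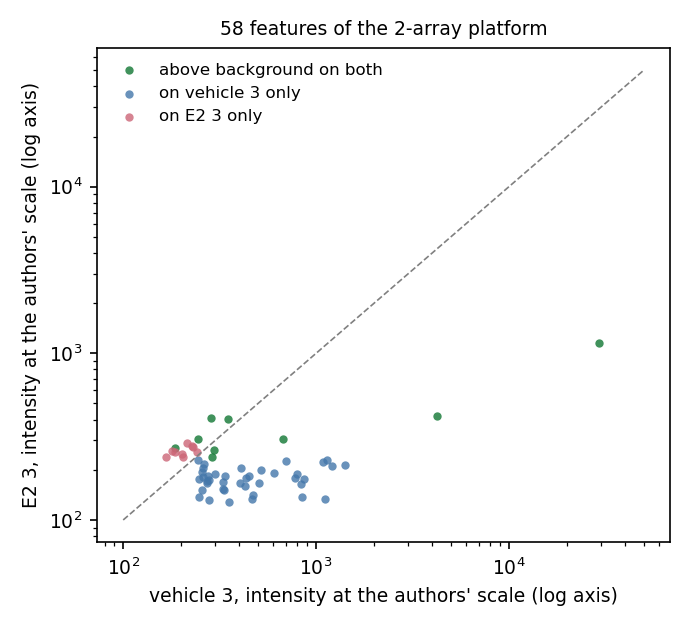
Intensity at the authors' scale of the 58 features above background on at least 1 array of the 2-array platform, vehicle 3 (horizontal, log axis) against E2 replicate 3 (vertical, log axis). The dashed line marks equal values, and 45 of the 58 points lie below it.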

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

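An empty spot of vehicle 1 read 3443, against a median of 143.7 over the 194 empty spots of that array, a signal where none was printed. The same position read 197, 198 and 177 on the other 3 arrays of the platform. The spot that follows it in the file is a spot of the bright control feature. It has little bearing on the threshold for background, which uses a percentile of the empty spots.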

How the results depend on the processing

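The number of features called on the 4-array platform stayed at 0 (limma, adjusted p under 0.05) under cyclic loess, other filters on dim features, the trended robust variance model, a threshold of 0.10, normexp or a median plus 3 MAD filter (both chosen after seeing the data), and each array left out (0 to 0). The smallest adjusted p over these alternatives and the blocked fits ran from 0.0602 to 0.604. It became 44 with median centring, 17 with no normalization between arrays and 29 with the authors' processed values, all lower with E2. Among alternatives chosen after seeing the data it became 34 lower when arrays were centred on the control feature, 3 higher with the median of the spots, and 1 higher when net signal was centred on the detected features. Quantile normalization, cyclic loess and centring on the detected features remove by construction a shift shared by most detected features. The share of features lower with E2, 62.5% in the main setting, was 99.1% with median centring, 97.3% with no normalization, 98.2% with the authors' values, 97.3% with control centring, 51.0% with no filter, 55.0% for features above background on every array, 66.3% with centred net signal, 58.0% with the median of spots, and 57.1% to 63.4% with an array left out. On the 2-array platform the 63.8% became 79.3% with median centring or with no normalization, 77.6% with the authors' values, 43.0% with no filter, and 0% for the 9 features above background on both arrays. The sign turned for BM10206 and BM10653, which were at -0.53 and -0.44 with median centring, -0.46 and -0.37 with no normalization, -0.52 and -0.43 with the authors' values (the block gave the same differences), and -0.47 and -0.37 with control centring. No other named difference changed sign.

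No label says that the replicate numbers pair animals. Differences between replicates 1 and 2 in the vehicle and E2 groups correlated at -0.26 across features, while the features with spots left out by the authors matched by number. With the replicate block 0 features were called in the main setting, and with the authors' values the count went from 29 to 0. A crossed pairing, added later, called 0. The fit over all 6 arrays, the fit without a platform term, the list tests, and the alternatives on probes of other species and on a second signal column were not run, for want of such data. Signal over background limits the folds of features near background, which are understated where no background is subtracted.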

Other observations

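The tests of explanations for the fall in overall signal were chosen after the result was seen, and the test on simulated 4-fold changes was set before its result was seen.

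The detected features of the 4-array platform were lower on the E2 arrays wherever the scaling followed the background. A weaker scan of the E2 arrays is argued against on that platform by the bright control feature. Its raw log2 signal differed by 0.0096 between the groups (SD over spots 0.12), while the median of the other features differed by -1.37. The files do not say what this feature is, so it cannot decide whether the sample RNA hybridised more weakly. On the 2-array platform the control feature was -0.86 with E2 and the median of the 9 features above background on both arrays -0.81, so a weaker scan or hybridisation could account for that median. The closeness of these values depends on PS20139, which was lower with E2 in raw net signal but higher in the authors' values with spots left out. An unequal amount or labelling of small RNA on single arrays may also account for the pattern. From raw intensities, as for the control, the largest difference of array medians (log2 net signal) within a group was 1.30 times that between groups. At the authors' scale the array medians differed by 1.43 between the E2 arrays and by 1.20 between the groups. As a median over the 80 features, however, the E2 arrays differed by 1.29 and the groups by 1.43. Which difference was larger thus depends on the statistic, but in each the E2 arrays differed by almost as much as the groups or by more. The 4 arrays allow only 3 splits, too few for a share under 0.05, and the real split had a median difference of 1.43 against 0.85 for the highest other; an E2 effect on miRNA abundance, or on the share of small RNA in total RNA, stays open and was not tested.

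A lack of single features past the threshold after quantile normalization may reflect the small number of arrays. In simulations at the real spread, 88.8% of 4-fold changes in 12 of the 112 features were found. That argues against this reason only for changes of that size in total intensity, because the changes were added with background included. A 4-fold change in miRNA abundance near background moves total intensity by less, so for such features the simulation cannot decide. Of 2-fold changes simulated in the same way, 53.4% were found. Unchanged features were called as well, a mean of 1.36 per simulation with 4-fold changes and 0.58 with 2-fold changes. When all 112 features were simulated 2-fold lower in net signal, 55.2% were called with median centring, and the median count with quantile normalization was 0. This simulation gave arrays of a group no difference in brightness, unlike the real arrays. The 55.2% therefore cannot be taken as the power to see such a fall here. When no group effect was simulated but each array's signal varied at random with the SD seen within groups (0.743 on the log2 scale), median centring gave calls in 21 of 100 simulations and 20 or more calls in 10 of them. That SD came mainly from the E2 arrays, with raw median net signals of 212.5 and 593.9, against 760.7 and 808.1 on the vehicle arrays.

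The features with spots that the authors left out matched between arrays of the same replicate number. Whether the same spots of these features were left out was not compared. All 16 features with left-out spots on vehicle 1 were also those of E2 replicate 1, the 29 of vehicle 2 were all among the 30 of E2 replicate 2, and 9 were shared between the 10 of vehicle 3 and the 9 of E2 replicate 3. Arrays of different numbers on the 4-array platform shared 2.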
